A study of Mus musculus with 13 samples.

How the data were processed

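Gene expression was measured in 13 samples of sorted mouse cells, 1 array per sample, from biotin-labelled cRNA hybridised to an Affymetrix array of 45101 probe sets. All mice carried MMTV-PyMT, a transgene that drives mammary tumours. The labels placed the samples in 6 groups. Splenic dendritic cells (n = 2) and tumour-associated macrophages labelled population I (n = 2) came from mice of 20 weeks. Mammary tissue macrophages with high CD11b (n = 2) and tumour-associated macrophages with low CD11b (n = 3) came from mice of 16 weeks. Cells of mice lacking Rbpj in CD11c-expressing cells (n = 2) and control tumour-associated macrophages with floxed Rbpj and no Cre in the label (n = 2) came from mice of 20 weeks. Rbpj is the DNA-binding partner of the Notch receptors. The gates of the last pair differed in the labels: knockout cells were sorted as CD45+B220-MHCII+, and control cells as MHC class II high and CD11b low within CD45+B220-.

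The values were used as the authors deposited them, on a log2 scale, 1 value per probe set and array; RMA and limma are named in the submitters' processing notes, without versions. RMA subtracts background, equalises array distributions and summarises probes on the log2 scale, so weak signals are compressed toward a floor and a difference of weak genes is understated. Whether all arrays were normalized together is not given in the sources used here, nor is a genome build. Array medians lay between 4.28 and 4.33 in the knockout and control samples and between 5.59 and 5.68 in the others. Sorted values of the knockout and control arrays differed from those of the dendritic cell set by up to 1.18 on average, against at most 0.0515 among themselves, so that set was on a scale of its own. The sets of 16 weeks and of dendritic cells differed by up to 0.191, no more than arrays within the former (0.198). The 3 main comparisons each stay within one set.

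Of the probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 were unnamed here; those with several or none were left out, as were 64 control probe sets. Symbols were checked through gene identifiers and 0 changed. Each gene was represented by its probe set of highest mean over all arrays, which gave 18193 genes, of which 9010 had more than 1 probe set. One limma model (limma 3.58.1, R 4.3.3) with a mean per group was fitted to all 13 arrays with eBayes, leaving 7 residual degrees of freedom per gene before moderation. P-values were adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 counted as passing. The contrasts were tumour against mammary tissue macrophages, Rbpj knockout against control, tumour macrophages against splenic dendritic cells, and the knockout difference minus the difference of mammary tissue from tumour macrophages. An F test among the 3 tumour macrophage groups crosses the array sets and serves only as a yardstick of set differences. Differences are given as log2 difference ± SE from this model, and group levels as mean ± SD.

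For gene groups, 32 lists of cell type markers and pathways were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over lists. Fry tests whether a list's genes move, on balance, one way and compares them with no other genes. Members were counted as passing over all genes tested and, separately, adjusted over the list alone. Several lists share members, alternative activation most of all, with 23 of its 30 measured genes also in another list. The 200 genes of largest difference in each direction between tumour and mammary tissue macrophages were also tested as sets in the other comparisons. Named genes are the 8 largest differences in each direction among genes that passed, did not overlap between groups and reached a mean of 7 in the higher group; 15 genes fixed in advance, among them Rbpj, Hes1, Itgam, Itgax and Vcam1; and up to 4 members of smallest p from each list described. Genes outside that rule are named as such. Tests, lists, this rule and most alternatives were fixed before the data were examined.

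One step was corrected after list results had been seen. The matching of list symbols first accepted an alias even where the listed symbol is the current name of a different gene, which put Trh in place of Trf and Pigq in place of Gpi1. Such matches were dropped, which altered 7 symbols in 7 lists. The CD8+ type dendritic cell list between tumour and mammary tissue macrophages went from 9 to 8 genes higher and from a median of 1.24 to 1.12. In the knockout its camera adjusted p went from 0.00251 to 0.0462. The first matching was kept as an alternative. Weights per array set were likewise added as an alternative after the data had been seen.

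Replicates correlated across genes with r between 0.978 and 0.993, and no pair was identical. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. An exact permutation test of a single gene could not go below p = 0.2 with 3 against 2 samples or 0.333 with 2 against 2, so single genes rest on limma's pooled spread. The actin control probe sets were brighter at the 3′ than at the 5′ end by 5.11 to 5.45 in the dendritic cell set, by 0.71 to 1.42 in the mammary tissue macrophage set and by 0.98 to 1.24 in the Rbpj set, so RNA or amplification differed between sets.

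On simulated values with known changes added to 200 of 18193 genes, genes changed by a log2 difference of 1 were recovered in 61.2% of cases between tumour and mammary tissue macrophages, 34.3% between knockout and control and 46.3% between tumour macrophages and dendritic cells; for a difference of 2 the shares were 95.5%, 89.6% and 91.0%. Wrong calls made up 4, 6.37 and 4.85% of calls. These shares hold for the simulated spread only. The measured median residual SD was 0.256 in the mammary tissue macrophage set, 0.160 in the dendritic cell set and 0.158 in the Rbpj set. With such unequal spread, recovery and wrong calls in the measured values may differ from these shares. Alternatives were quantile normalization of all arrays, genes above the median of mean level, the mean over probe sets, only the arrays compared, a prior with trend, the replicate number as a block, a 2-fold minimum, 100 or 400 genes per set and each array left out.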

Results

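Macrophages and dendritic cells of mice with MMTV-PyMT mammary tumours were profiled to place tumour-associated macrophages (TAM) relative to mammary tissue macrophages (MTM) and splenic dendritic cells, and to see what deletion of Rbpj, the transcriptional mediator of Notch signalling, changed in tumour macrophages. The 13 arrays comprised 3 TAM and 2 MTM samples of 16 weeks, 2 TAM and 2 splenic dendritic cell samples of 20 weeks, and 2 Rbpj knockout and 2 control samples of 20 weeks.

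Between TAM and MTM at 16 weeks, MTM had higher levels of many resident macrophage and classical monocyte genes, although the camera calls of both lists were lost with an estimated correlation. Lyve1, a hyaluronan receptor of tissue macrophages, fell by 6.03 ± 0.56 on the log2 scale in TAM, from 10.65 ± 0.31 (SD, n = 2) to 4.63 ± 1.03 (SD, n = 3). The chitinase-like gene Chil3 fell by 6.52 ± 0.80, fibronectin (Fn1) by 5.84 ± 0.52 and the endothelin receptor Ednrb by 5.34 ± 0.36. TAM had more Vcam1, an adhesion molecule for integrins, with a difference of 3.05 ± 0.33 and a level of 12.27 ± 0.12 (SD, n = 3) against 9.22 ± 0.03 (SD, n = 2). They also had more Mmp13, a collagenase (4.16 ± 0.38), and Cd207, or langerin (4.32 ± 0.49). In all, 1900 of 18193 genes passed limma with Benjamini-Hochberg adjustment, 1063 higher and 837 lower in TAM; the count was 983 with only these 5 arrays in the fit.

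Itgam, which encodes the CD11b of the gates, fell by 2.52 ± 0.38 in TAM, and Itgax, which encodes CD11c, was 2.89-fold higher. The mannose receptor Mrc1 fell by 2.05 ± 0.33 and the chemokine receptor Ccr2 by 1.98 ± 0.45. The log2 difference was 0.03 ± 0.15 for H2-Aa, 0.22 ± 0.18 for H2-Ab1, 0.30 ± 0.28 for Cd74, 0.19 ± 0.15 for Ptprc, 0.36 ± 0.18 for Csf1r, 0.68 ± 0.36 for Flt3, 0.03 ± 0.23 for Zbtb46 and -0.04 ± 0.39 for Mertk, none of which passed.

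**Figure D1:**
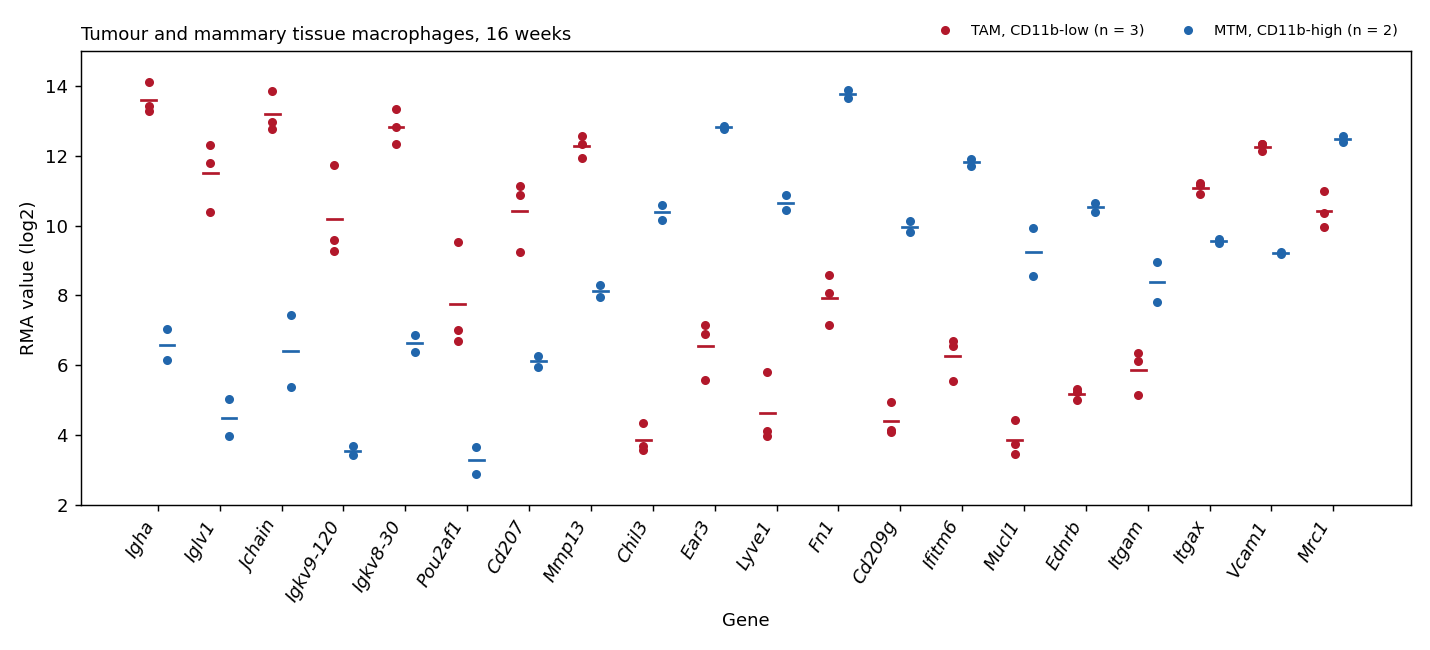
RMA values (log2) per array for the 16 genes of largest difference under the naming rule and for Itgam, Itgax, Vcam1 and Mrc1 in TAM (red, n = 3) and MTM (blue, n = 2); points are arrays and bars are group means. Igha averaged 13.62 in TAM and 6.59 in MTM, and Chil3 3.87 and 10.38.

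Of 30 measured resident tissue macrophage genes, 19 fell, 2 rose and 9 did not pass, with a median log2 difference of -1.76 (20 lower and 2 higher adjusted over the list alone). Besides Lyve1 and Ednrb, the lectin Cd209f fell by 4.61 ± 0.32 and Cd209b by 2.40 ± 0.16. Of 17 classical monocyte genes, 12 fell and 0 rose, with a median of -2.09 (14 lower adjusted over the list alone). Among them Ifitm6 fell by 5.56 ± 0.58 and the C-type lectin Clec4e fell by 3.62 ± 0.35. Camera gave adjusted p = 7.08e-13 and 2.34e-11 for these lists at the preset correlation, and adjusted p = 0.274 and 0.176 with an estimated correlation. Fry, which compares a list with no other genes, gave adjusted p = 0.00161 and 0.00131. Of 30 alternative activation genes 13 fell and 2 rose (14 and 3 adjusted over the list alone), at a median of -0.66. Camera gave adjusted p = 0.000690, and adjusted p = 0.320 with an estimated correlation, and fry gave adjusted p = 0.0222. The chemokine Ccl24 fell by 3.95 ± 0.52 and Myc rose by 1.36 ± 0.18.

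Markers of CD8+ type dendritic cells went mostly the other way: 8 of 15 rose, 1 fell and 6 did not pass, at a median of 1.12 (11 and 1 adjusted over the list alone; camera adjusted p = 3.78e-05, adjusted p = 0.274 with an estimated correlation). Cadm1, a cell adhesion molecule, rose by 2.75 ± 0.24, Tlr3, a receptor for double-stranded RNA, by 2.63 ± 0.27, and the transcription factor Irf8 by 2.27 ± 0.25, while Batf3 fell by 1.34 ± 0.23. In the CD11b+ dendritic cell list 7 of 17 fell and 0 rose, at a median of -0.41, with Cd209a falling by 3.70 ± 0.33 (7 lower adjusted over the list alone; camera adjusted p = 0.000383, adjusted p = 0.320 with an estimated correlation). Of 27 conventional dendritic cell genes 4 rose and 1 fell (8 and 2 adjusted over the list alone), at a median of 0.26 (adjusted p = 0.338 with an estimated correlation). Of 30 core macrophage genes 4 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.492 with an estimated correlation). Fry gave adjusted p = 0.00300 for the CD8+ type and 0.00756 for the CD11b+ dendritic cell list. For the conventional dendritic cell and core macrophage lists fry gave adjusted p = 0.0484 and 0.0658.

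In the Notch list 7 of 41 genes rose and 2 fell (10 and 2 adjusted over the list alone), at a median of 0.04. Camera gave adjusted p = 0.0445, and adjusted p = 0.320 with an estimated correlation. Il2ra, the interleukin-2 receptor alpha chain, rose by 3.93 ± 0.27, the Deltex gene Dtx4 by 2.17 ± 0.22 and the Notch target Hes1 by 1.84 ± 0.34, whereas Rbpj itself fell by 0.71 ± 0.16. Of 28 adhesion genes 9 rose and 2 fell (9 and 5 adjusted over the list alone; adjusted p = 0.320 with an estimated correlation), with the integrins Itga6 and Itgb5 rising by 1.85 ± 0.25 and 1.78 ± 0.16. Chemokines and their receptors divided, with 8 of 34 higher and 10 lower (11 and 10 adjusted over the list alone): Cxcl16 rose by 1.78 ± 0.17 and Cx3cr1 by 1.57 ± 0.18, and Ccl8 and Ccl7 fell by 3.98 ± 0.43 and 2.89 ± 0.35. Matrix genes divided likewise, 6 of 27 higher and 9 lower, the same adjusted over the list alone, with Timp1 falling by 2.88 ± 0.23. Among 24 suppressive and checkpoint genes 3 rose and 3 fell (5 and 4 adjusted over the list alone), Havcr2 (TIM-3) rising by 2.33 ± 0.20 and Cd200r1 falling by 2.92 ± 0.49. Of 27 classical activation genes 8 rose and 4 fell, the same adjusted over the list alone, among them Il12b, which rose by 3.57 ± 0.58, and Ccl2, which fell by 2.07 ± 0.31. No member of the cell cycle list (37 genes) or the MHC class I list (15 genes) passed. Fry gave adjusted p = 0.00473, 0.00272 and 0.0123 for the Notch, adhesion and matrix lists. For the chemokine, checkpoint and classical activation lists fry gave adjusted p = 0.929, 0.376 and 0.376.

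Immunoglobulin genes had the largest positive differences under the naming rule. Igha was higher in TAM by 7.02 ± 0.53, Igkv8-30 by 6.21 ± 0.33, Jchain, which joins secreted antibodies, by 6.79 ± 0.65 and the B-lineage coactivator Pou2af1 by 4.47 ± 0.86. In the B cell list 4 of 18 genes rose and 0 fell, at a median of 0.86 (6 higher adjusted over the list alone; camera adjusted p = 0.00210, adjusted p = 0.526 with an estimated correlation), although both gates excluded B220. In the plasmacytoid dendritic cell list 4 of 12 rose and 0 fell, with Siglech rising by 1.98 ± 0.30 (4 higher adjusted over the list alone; adjusted p = 0.216 with an estimated correlation).

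Rbpj, the deleted gene, was read by 3 probe sets in the knockout, with log2 differences of -0.53, -0.51 and -0.68 from control; the brightest read 8.98 and 8.90 in the knockout arrays and 9.56 and 9.67 in the control arrays. It did not pass (limma, Benjamini-Hochberg adjusted p = 0.338). In the other sets, which are not comparable in level, it read 10.52 and 10.75 in dendritic cells, 11.42 and 11.37 in TAM of population I, 11.36 and 11.50 in MTM, and 10.90, 10.59 and 10.67 in TAM of 16 weeks. Where these probe sets lie relative to the deleted part is not known here, so they do not check the genotype labels. Hes1 had a difference of -1.67 ± 0.38, which did not pass either (adjusted p = 0.213, limma).

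In cells of Rbpj knockout mice, Adamdec1, a secreted metalloprotease, fell by 4.26 ± 0.41 from 8.54 ± 0.54 (SD, n = 2) to 4.28 ± 0.27 (SD, n = 2), and Vcam1 fell by 2.63 ± 0.36. The natural killer receptor family gene Klra17 fell by 3.43 ± 0.43 and Acp5, tartrate-resistant acid phosphatase, by 2.23 ± 0.19. Fn1 rose by 4.27 ± 0.57, to 11.07 ± 1.25 (SD, n = 2) from 6.81 ± 0.56 (SD, n = 2), and Ednrb rose by 3.10 ± 0.39. In total 14 genes passed limma with Benjamini-Hochberg adjustment, 4 higher and 10 lower, and 589 had an unadjusted p under 0.05. The others that fell were Fam189a2 (-1.74), Dgat2 (-1.61), Pdgfc (-1.27) and Kctd14 (-1.19), and, outside the naming rule and chosen after their values were seen, Stra6l (-2.33) and Lrrc4c (-2.07); Mefv (2.17) and Olr1 (2.33), also outside the rule, rose. The count depended on single arrays, from 1 without control replicate 1 to 32 without each TAM replicate of population I. It was 87 with weights per array set, where 51 were higher and 36 lower, so the excess of lower genes turned round. With only these 4 arrays it was 11, 5 higher and 6 lower, of which 5 were among the 14; Fn1 and Ednrb were not. It was 0 with the replicate number as a block (limma; 610 genes at an unadjusted p under 0.05).

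The gates of knockout and control differed, and Itgam and Itgax, the latter the gene of the CD11c that marks the cells of the deletion, had differences of 1.66 ± 0.41 and -1.17 ± 0.23 that did not pass. Both passed with weights per array set (adjusted p = 0.0417 and adjusted p = 0.0278). Of 17 classical monocyte genes, 1 rose, 0 fell and 16 did not pass, at a median of 1.59, whereas 9 rose adjusted over the list alone. Over all genes 8 rose with weights per array set and 3 with only the arrays compared. Camera gave adjusted p = 1.10e-24 at the preset correlation and adjusted p = 0.0188 with an estimated correlation, and fry gave adjusted p = 0.0357. Members that did not pass over all genes included F13a1 at 5.02 ± 0.88, S100a4 at 3.81 ± 0.64 and Gda at 3.79 ± 0.62, which passed with weights per array set. The knockout arrays were uneven, with F13a1 at 10.84 in replicate 1 and 9.05 in replicate 2, and Gda at 10.41 and 9.12. Of 30 resident tissue macrophage genes 1 rose (14 higher and 1 lower adjusted over the list alone), at a median of 0.45 (camera adjusted p = 7.92e-18, adjusted p = 0.145 with an estimated correlation); Lyve1 stood at 3.18 ± 0.62 and Cd163 at 3.87 ± 0.80, neither passing. With weights per array set both passed (adjusted p = 0.0222 for each), and 6 of the list rose and 1 fell. Of 30 alternative activation genes 1 rose, Fn1, the same gene that rose in the classical monocyte list. The median was 0.74 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.145 with an estimated correlation). Retnla stood at 5.50 ± 1.14 and Chil3, a member of the classical monocyte list too, at 4.22 ± 0.87, neither passing. With those weights both passed (adjusted p = 0.0312 and adjusted p = 0.0420), and 5 of the list rose. For chemokines and receptors 0 of 34 passed, 2 rose with those weights and 9 rose adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). The CD11b+ and CD8+ type dendritic cell lists had medians of 0.18 and -0.29 (camera adjusted p = 0.342 and adjusted p = 0.672 with an estimated correlation). In the CD11b+ list 0 of 17 passed, and 4 rose and 1 fell adjusted over the list alone. Those that rose were S100a4, Cd209a, Clec10a and Itgam, the last the CD11b gene of the differing gates. The gene that fell was Rbpj, the deleted gene itself. Over all genes 3 of that list rose with weights per array set and 1 with only the arrays compared. Cell cycle genes had a median of 0.21 (camera adjusted p = 0.816 with an estimated correlation). Beyond the classical monocyte list, fry called none of these lists. It gave adjusted p = 0.258 for resident tissue macrophage and for alternative activation genes, and 0.412 for chemokines and receptors. For the CD11b+ and CD8+ type lists fry gave adjusted p = 0.814 each, and for cell cycle 0.892.

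None of 41 Notch list genes passed between knockout and control. Adjusted over the list alone 2 fell, Hes1 and Rbpj, the latter the deleted gene itself. With weights per array set 1 of the 41 passed, Hes1, which fell by 1.67 (limma, adjusted p = 0.0462). In the matrix list 1 of 27 rose, again Fn1 (7 higher and 3 lower adjusted over the list alone). Mmp2 stood at -2.55 ± 0.43 and Mmp13 at -2.13 ± 0.41, neither passing. With weights per array set both passed (adjusted p = 0.00564 and adjusted p = 0.0357), and 2 of the list rose and 2 fell. Mmp2 also passed with only the arrays compared (adjusted p = 0.0451). H2-Aa, H2-Ab1, Cd74 and Ptprc had differences of -0.08 ± 0.17, -0.23 ± 0.19, -0.36 ± 0.30 and -0.15 ± 0.17. Csf1r, Mertk, Ccr2, Mrc1, Flt3 and Zbtb46 had differences of -0.04 ± 0.19, -0.16 ± 0.42, 1.68 ± 0.50, 0.99 ± 0.36, 0.50 ± 0.40 and 0.56 ± 0.25; none passed.

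The knockout difference was compared with the difference between macrophage subsets, which came from other arrays. Of the 10 genes that fell in the knockout, 8 were among the 1063 higher in TAM than in MTM, against 0.584 by independent draws, and all 4 that rose were among the 837 higher in MTM, against 0.184. Both comparisons used the same estimate of spread for each gene, so their calls were not independent and these expected counts may be too low. The 200 genes most raised in MTM had a median of 1.25 in knockout minus control, and 196 of them lay above 0 (camera p = 0.00149 with an estimated correlation). The 200 most raised in TAM had a median of -0.42, with 28 above 0 (camera p = 0.00317 with an estimated correlation). Without knockout replicate 1 these medians were 0.765 and -0.276, and without replicate 2 they were 1.68 and -0.574. Across all genes, which are not independent replicates, both differences correlated with Pearson r = -0.592 and Spearman rho = -0.376.

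**Figure D2:**
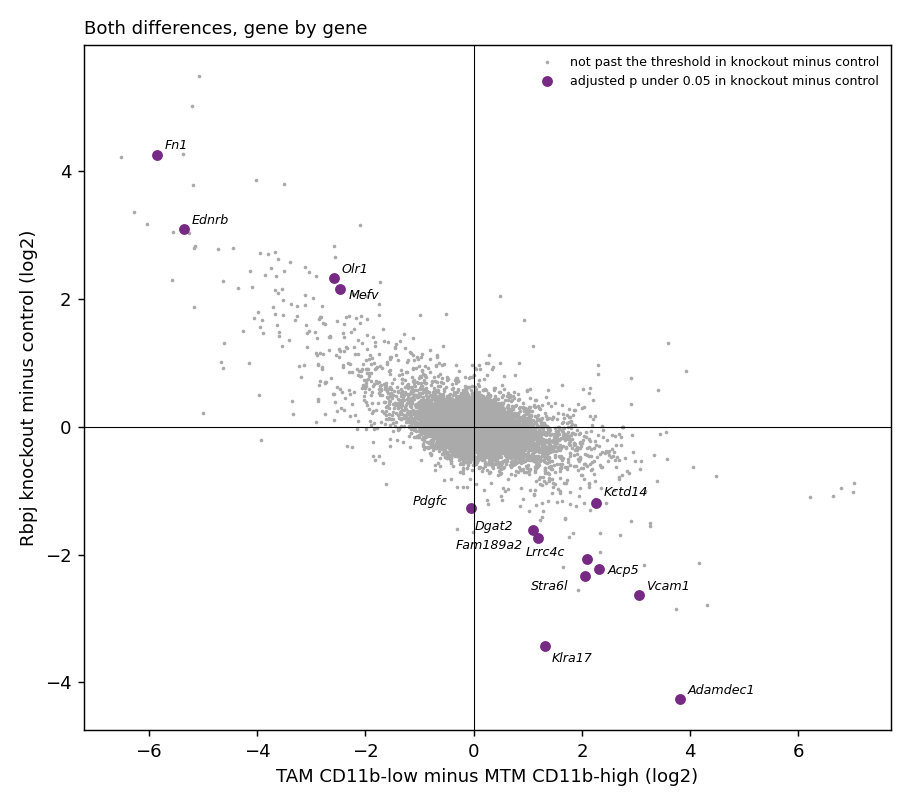
Each point is 1 of 18193 genes, with TAM minus MTM (log2) on the horizontal axis and Rbpj knockout minus control (log2) on the vertical axis; the 14 genes that passed in the knockout are purple and named. Fn1 lies at -5.84 and 4.27, and Adamdec1 at 3.81 and -4.26.

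Against splenic dendritic cells, TAM of population I at 20 weeks had the higher levels of macrophage genes and the lower levels of dendritic cell genes. Cell type and organ differ together in this comparison, so their effects cannot be told apart. Of 30 core macrophage genes 26 rose, 0 fell and 4 did not pass, at a median of 2.22 (28 higher adjusted over the list alone). The Fc receptor gene Fcgr1 rose by 4.49 ± 0.23, the complement genes C1qa and C1qc by 3.79 ± 0.18 and 3.75 ± 0.23, and Mertk, a receptor for apoptotic cells, by 2.54 ± 0.42. Of 27 conventional dendritic cell genes 16 fell and 0 rose, at a median of -2.21 (18 lower adjusted over the list alone). Flt3, a growth factor receptor of dendritic cells, fell by 4.04 ± 0.40, and the transcription factor Zbtb46 by 3.84 ± 0.25. Camera called both lists, each with adjusted p = 0.00906 with an estimated correlation. In all, 2232 genes passed limma with Benjamini-Hochberg adjustment, 1347 higher and 885 lower in TAM; the count was 834 with only these 4 arrays in the fit.

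Matrix remodelling genes rose in 13 of 27 cases and fell in 3 (16 and 5 adjusted over the list alone; adjusted p = 0.0210 with an estimated correlation), with Mmp13 higher by 6.16 ± 0.41, Mmp2 by 4.89 ± 0.43 and Timp2 by 3.51 ± 0.19. In the lipid and lysosome list 18 of 32 rose and 2 fell (20 and 2 adjusted over the list alone; adjusted p = 0.0647 with an estimated correlation), among them Apoe by 4.02 ± 0.26 and the cholesterol exporter Abca1 by 3.52 ± 0.25. Of 30 resident tissue macrophage genes 12 rose and 4 fell (14 and 4 adjusted over the list alone; adjusted p = 0.248 with an estimated correlation), with Stab1 at 4.74 ± 0.23. Of 30 alternative activation genes 8 rose and 2 fell (10 and 4 adjusted over the list alone; adjusted p = 0.281 with an estimated correlation), with Mrc1 at 2.85 ± 0.36. Of 34 chemokine genes 13 rose and 3 fell (18 and 5 adjusted over the list alone; adjusted p = 0.140 with an estimated correlation), with Cmklr1 at 4.07 ± 0.20. The integrins Itgb5 and Itga6 rose by 4.63 ± 0.17 and 4.21 ± 0.27. Csf1r, the receptor for macrophage growth factor, rose by 0.98 ± 0.19. Itgam, Itgax, Vcam1, Ccr2 and Hes1 had differences of 0.78 ± 0.41, -0.05 ± 0.23, 1.03 ± 0.36, 1.40 ± 0.50 and 0.38 ± 0.38, and H2-Ab1, Cd74 and Ptprc of 0.05 ± 0.19, -0.16 ± 0.30 and -0.37 ± 0.17; none of these 8 passed.

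Interferon genes rose in 12 of 28 cases (17 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation), with Ifi204 at 2.76 ± 0.32. Hypoxia and glycolysis genes rose in 11 of 29 (14 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation), with the carbonic anhydrase Car12 at 3.32 ± 0.51. Of 37 cell cycle genes 13 fell and 0 rose (18 lower adjusted over the list alone; adjusted p = 0.281 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at -1.49 ± 0.30. In the CD11b+ dendritic cell list 11 of 17 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation), with Tbx21 at -4.77 ± 0.48. In the CD8+ type list 4 of 15 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation), with Ly75 at -3.42 ± 0.28 and Cadm1 at 2.04 ± 0.26. In the Notch list 10 of 41 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation): Rbpj rose by 0.76 ± 0.17 and Dtx4 by 2.68 ± 0.24, and Dtx1 fell by 5.09 ± 0.36. Of MHC class II genes, H2-Oa and H2-Ob, which restrain peptide loading, fell by 3.21 ± 0.33 and 3.37 ± 0.34, and H2-Aa had a difference of -0.11 ± 0.17. In the MHC class II list 2 of 17 rose and 5 fell (2 and 6 adjusted over the list alone; adjusted p = 0.281 with an estimated correlation).

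Genes of other cell types moved as well. Epithelial genes rose in 14 of 24 cases and fell in 0, at a median of 2.03 (18 higher adjusted over the list alone; adjusted p = 0.147 with an estimated correlation). The milk protein gene Csn3 had the largest difference of the rule, 8.98 ± 0.69, with 13.53 ± 1.11 (SD, n = 2) in TAM and 4.56 ± 0.46 (SD, n = 2) in dendritic cells, and the keratins Krt8 and Krt18 rose by 5.39 ± 0.64 and 4.83 ± 0.51. Also among the largest were Clca3a2 at 7.25 ± 0.63, Rnase4 at 6.88 ± 0.29, Ang at 6.57 ± 0.29 and Pmepa1 at 6.43 ± 0.29. B cell genes fell in 12 of 18 cases and rose in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.210 with an estimated correlation), with Ms4a1, or CD20, at -5.17 ± 0.98. Neutrophil genes fell in 7 of 15 (7 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation), with Ngp at -6.08 ± 0.46. T cell genes fell in 5 of 18 (5 adjusted over the list alone; adjusted p = 0.248 with an estimated correlation), with Icos at -4.81 ± 0.55. This pair of gates did not name B220.

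The genes of largest difference between TAM and MTM were tested here too. The 200 most raised in TAM over MTM had a median of 1.23 in TAM minus dendritic cells, with 149 above 0 (camera p = 0.00651 with an estimated correlation). The 200 most raised in MTM had a median of 0.26, with 117 above 0 (camera p = 0.100 at the preset correlation). With 1 array left out that median ranged from 0.0333 to 0.573, and the set passed in some of these fits. Across genes both differences correlated with Pearson r = 0.108. Among the 3 TAM groups 16865 genes passed an F test, but array set, age and gate cannot be told apart there, and the count describes the sets.

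**Figure D3:**
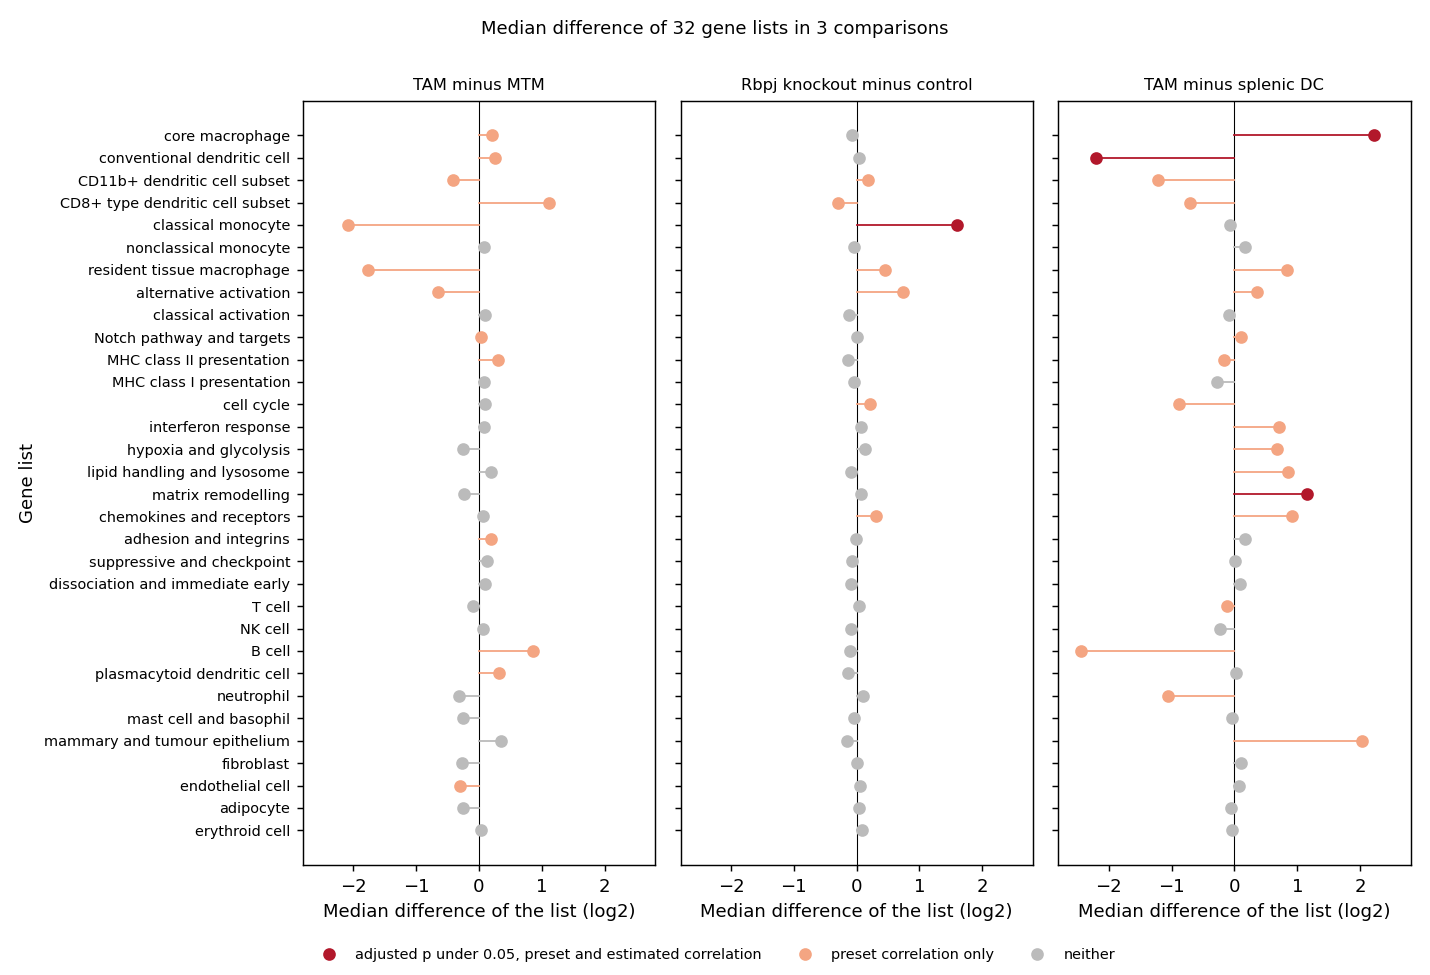
Median log2 difference of each of 32 gene lists in TAM minus MTM, Rbpj knockout minus control and TAM minus splenic dendritic cells; dark red marks lists called by camera at both correlations, orange at the preset correlation only, and grey at neither. The counts called at both were 0, 1 and 3.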

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

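Of the tests in this part, those of dilution, of the limit on single genes, of the knockout array left out, of any share and of B cells, and the repeat of the mixed share without immunoglobulin genes, were chosen after the result was seen; those of the mixed share and of plasma cells were not. The difference between knockout and control was set against that between MTM and TAM by testing the difference of both. It passed for 108 genes, 83 positive and 25 negative (limma, Benjamini-Hochberg), for 5 with the replicate number as a block and for 15 to 189 with 1 array left out. Of the 83 positive genes 3 have immunoglobulin symbols. A gene passes where its knockout change departs from the whole MTM difference, so a large subset difference with little knockout change is enough. Both differences come from array sets on separate scales, and many named genes were chosen for their TAM and MTM difference on the same arrays. By itself the difference of both therefore does not show a knockout effect. Among the named genes it was -1.39 for Rbpj, which had lower values in the knockout but higher ones in MTM, and -1.33 for Pdgfc, which fell in the knockout and differed by -0.06 between TAM and MTM. Several other named genes were lower in MTM than in TAM with smaller or opposite differences in the knockout. For these the value was 4.80 for Il2ra, which had the smallest p, 2.34 for Tlr3, 2.11 for Itga6, 2.11 for Ermap, 1.99 for Cadm1 and 1.91 for Havcr2. It was 1.71 for Dtx4, 1.54 for Cx3cr1, 1.504 for Itgb5 and 1.37 for Cxcl16. Of immunoglobulin-related genes it was 6.14 for Igha, 5.84 for Jchain, and 5.57 and 5.11 for a pair of kappa variable genes. Named genes higher in MTM with smaller differences in the knockout were Cd209f (-3.29), Fxyd2 (-3.13), Cd209b (-2.13) and Timp1 (-1.89).

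The first pattern is the shift of knockout cells toward MTM, which MTM in the knockout sort might produce, since its gate differed from that of the control in the labels (whether it was wider in practice is not known); from 74 genes at least 8-fold higher in MTM, the share of such cells was estimated at 21.5% (38.6% in knockout replicate 1 and 10.7% in replicate 2), which predicts a median fall of -0.32 for 25 genes at least 8-fold higher in TAM. The observed median was -0.88, a gap of -0.56 (95% bootstrap interval -0.81 to -0.25). The bootstrap resampled genes and not arrays, so the interval leaves out the spread between knockout replicates 1 and 2. Moreover, 8 of the 25 are immunoglobulin and plasma cell genes, which another cell type may bring and the test as written did not foresee. Without them, a check made afterwards, the gap was -0.34 (-1.79 to 0.19), so admixture of MTM and a change in the TAM cannot be told apart for the genes that rose. For the genes that fell, a pair of tests was undecided: of 8 genes high in TAM over both MTM and dendritic cells, 2 fell beyond their common median of -0.36, and of the 10 genes that fell, 2 (Acp5 and Adamdec1) went past -0.70, the most that a share of 38.6% allows, adjusted over all genes because the 10 were selected for their fall. A later test, added once these were known, took genes lower with 1 knockout array left out and measured them in that array. The falls were -2.01 to -4.07 in replicate 1 and -1.75 to -4.45 in replicate 2. All 8 of 8 went past the limit of the array's own share at the upper end of its interval (-1.004 and -0.197). At those shares this argues against MTM as the whole cause for Acp5, Adamdec1 and Stra6l, tested in both arrays. However, the same control arrays served the selection, and the share rests on MTM of another array set. A last test set the falls against the whole MTM difference, the most that any share allows. Acp5, Adamdec1 and Stra6l departed from it by 0.09 ± 0.25, -0.45 ± 0.56 and -0.27 ± 0.38, none passing over all genes. A share above those estimated is therefore not excluded for them. MTM as part of the cause or other cells in the gate stay open. MTM at any share would not lower Pdgfc. It fell beyond the MTM difference by 1.33 ± 0.26 (limma, adjusted p = 0.0481 over all genes). With 1 array left out this departure stayed between -1.14 and -1.52, with an adjusted p above 0.05 in 12 of 13 fits. Pdgfc was, however, higher by 3.29 in TAM of population I than in splenic dendritic cells. Dendritic cells in the knockout sort could therefore lower it, and this was not tested. For the other 6 genes admixture and loss of Rbpj cannot be told apart.

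The second pattern is the immunoglobulin excess of TAM over MTM, for which plasma cells or B cells in the tumour sort are candidate sources; the gates excluded B220, which plasma cells largely lose. Of 15 plasma cell markers other than Jchain, Mzb1 and Pou2af1, the median difference was 0.222 (camera p = 0.0453), as plasma cells would need, but the p was 0.121 with an estimated correlation, 3 were higher past the threshold, and Sdc1, a plasma cell surface marker, fell by 2.44, so this is weak. Of 10 B cell surface markers the median was 0.865 and 1 passed, which leaves B cells open. Igha stood at 13.29 to 14.11 in TAM and 6.16 to 7.03 in MTM. No biological explanation within macrophages was tested.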

How the results depend on the processing

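Array weights per set and the first symbol matching were chosen after the data were seen; the other settings were planned. Between TAM and MTM, 1900 genes became 1137 with a 2-fold minimum, 983 with only the arrays compared, 1056 with the replicate number as a block and 1040 with array weights per set, all 1040 of them among the 1900; leaving out 1 array gave 1329 to 2318. Between knockout and control, 14 became 7 after quantile normalization and 8 with the mean over probe sets (all among the 14), 0 with the replicate block (limma; 610 genes at an unadjusted p under 0.05) and 87 with array weights per set (51 higher and 36 lower), which include the 14. With only the arrays compared it was 11 (5 higher and 6 lower), of which 5 were among the 14: Adamdec1, Klra17, Vcam1, Acp5 and Mefv. Leaving out 1 array gave 1 to 32: 1 and 5 without control replicates 1 and 2, 3 and 28 without knockout replicates 1 and 2, 9 without each MTM replicate and 32 without each TAM replicate of population I. Between TAM and dendritic cells, 2232 became 834 with only the arrays compared, and 1353 to 2324 with 1 array left out, among them 1353 without dendritic cell replicate 1 and 1477 without TAM population I replicate 2. The difference of differences went from 108 to 5 with the replicate block and to 15 to 189 with 1 array left out: 15 and 30 without control replicates 1 and 2, 25 without knockout replicate 2, 189 without MTM replicate 2, and 59 and 48 without TAM replicates 1 and 3. The F test among TAM groups gave 5764 genes after quantile normalization and 8239 among genes above the median of mean level, where fewer genes were tested, and 15240 to 17043 with 1 array left out. The MTM-raised set against dendritic cells, at 0.26 in the main analysis, passed at 0.263 with only the arrays compared, and ranged from 0.0333 to 0.573 with 1 array left out, passing at 0.573 without TAM population I replicate 2 and at 0.276 without TAM replicate 3 of 16 weeks. In the knockout the MTM-raised set ranged from 0.765 without knockout replicate 1 to 1.68 without replicate 2, and the TAM-raised set from -0.574 to -0.276, all passing. Where 1 array was left out of a pair, the lone array was assumed to vary like the other groups. A prior with trend kept every count within 1.5 times the one reported. Fewer arrays or degrees of freedom are part of the smaller fits, but the fit with array weights kept all 13 arrays. Its weights averaged 0.65 in the set of 16 weeks, 1.17 in the dendritic cell set and 1.46 in the Rbpj set. The median residual SD of these sets was 0.256, 0.160 and 0.158. A single spread for all sets is thus too small for TAM and MTM and too large for the knockout, the direction of the moves to 1040 and 87. Beyond that the cause was not tested. The labels do not state that replicate numbers pair samples, and with 2 pairs each the differences between replicates 1 and 2 correlated across genes with r = -0.328 for TAM and MTM, 0.205 for knockout and control and 0.264 for TAM and dendritic cells, so the block shares only a number.

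Of the gene lists, 2 reversed in the knockout, neither of them called in the main analysis (camera adjusted p = 0.811 for NK cell and adjusted p = 0.507 for dissociation genes). NK cell genes stood at a median of 1.17 among genes above the median of mean level. Only their brighter members remained there, and the minimum of 5 members per list was not applied again. Dissociation genes stood at 0.121 without knockout replicate 1 and -0.27 without replicate 2. The cause was not tested. With an estimated correlation 13 of 13 list calls were lost between TAM and MTM, 6 of 7 in the knockout and 15 of 18 against dendritic cells. The first symbol matching changed 0 list calls. Weak signals near the array floor limit all differences of dim genes.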

Other observations

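The test of 3′ bias in this part was chosen after the result was seen. Between TAM and MTM, 1 of 28 interferon genes rose, Ifit2 at 1.47 ± 0.24, 1 of 29 hypoxia and glycolysis genes rose and 3 fell, with Pfkp at -1.55 ± 0.31, and 1 of 32 lipid and lysosome genes rose and 2 fell, with Fabp5 at -1.20 ± 0.26. Nonclassical monocyte genes divided, 2 of 15 higher and 3 lower, with Ceacam1 at -2.85 ± 0.40 and Adgre4 at -2.91 ± 0.43. In the MHC class II list 2 of 17 rose and 1 fell, with H2-Ob at 1.84 ± 0.31 and H2-DMb2 at -2.06 ± 0.47 (adjusted p = 0.492 with an estimated correlation). In the dissociation list 2 of 26 fell, Ier3 at -1.05 ± 0.25 and Egr2 at -1.55 ± 0.43.

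Of other cell types in that comparison, 1 of 18 T cell genes fell, Cd2 at -4.44 ± 0.76, and 1 of 14 NK cell genes, Klrd1 at -1.43 ± 0.42. Of neutrophil genes 4 of 15 fell, with S100a9 at -2.57 ± 0.55, and of mast cell genes 2 of 13, Cpa3 at -1.62 ± 0.40 and Cma1 at -1.67 ± 0.43. One epithelial gene of 24 rose, Spint1 at 2.58 ± 0.22, and 1 fibroblast gene of 17, Fap at 1.70 ± 0.29. Of 16 endothelial genes Vwf fell, at -2.19 ± 0.41 (adjusted p = 0.338 with an estimated correlation for the list), of 11 adipocyte genes Fabp4 fell, at -1.45 ± 0.25, and of 8 erythroid genes Ermap rose, at 2.17 ± 0.26. The median, mean and test of a list differed in sign for 4 lists here, 6 in the knockout and 5 against dendritic cells, none of them called. In the knockout 0 members of the lists of other cell types passed (limma), whereas with weights per array set 1 epithelial gene (Spint1) and 1 fibroblast gene (Fap) fell and 1 adipocyte gene (Fabp4) rose. Against dendritic cells, 3 of 17 classical monocyte genes rose and 5 fell, 9 of 28 adhesion genes rose and 5 fell, 3 of 27 classical activation genes rose and 7 fell, and 5 of 24 suppressive and checkpoint genes rose and 4 fell. Of 15 MHC class I genes 3 fell there and 0 rose.

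A further pattern is the epithelial signal in TAM of population I, which may come from tumour cells or their RNA in the sort, although the gate required CD45. Of 24 epithelial genes 14 were higher than in dendritic cells and 0 lower, which is the pattern itself, and no separate test of such a source was made. The actin 3′ minus 5′ gap differed between these groups by 0.103, so this control showed no uneven RNA quality between them. The gap was large in both groups, from 5.11 to 5.45, and a single control transcript cannot exclude such unevenness. Csn3 averaged 13.53 in these TAM, against 10.15 in TAM and 8.62 in MTM of 16 weeks, where the difference of 1.53 ± 0.63 did not pass; levels are not comparable across array sets. Whether macrophages took up or expressed these transcripts was not tested, nor was whether the same source raised genes of other lists, such as hypoxia or matrix genes.

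The 2 knockout arrays differed from each other along the axis that separates MTM from TAM: across genes, the difference of replicate 1 from replicate 2 correlated with MTM minus TAM at r = 0.414, against 0.0530 for the control replicates. Genes are not independent replicates, and the 2 knockout arrays were not tested against each other gene by gene.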
